A study of Mus musculus with 6 samples.

How the data were processed

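RNA sequencing libraries of 4T1 cells, a mouse breast cancer line, were compared between cells given DMSO and cells given BRQ, with 3 libraries in each group. Groups and replicate numbers were taken from the labels. Per the labels' protocols, RNA was extracted with TRIzol and made into libraries by standard Illumina methods. Whether poly(A) or total RNA was sequenced is not given in the sources used here. Per the submitters' processing notes, fastp, HTSeq and the mouse build GRCm39 were used. The aligner, the annotation release, the strand setting and the versions of these tools are not given in the sources used here. Reads of overlapping or antisense genes, of near-identical gene copies and of genes with processed pseudogenes may therefore be shared among them.

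The authors deposited 1 table of FPKM for 18057 genes, each with its symbol, Entrez identifier, description, gene ontology terms and pathways, and replicates were not pooled. The table also held 8 columns of values that belong to no sample of this series, and these were not used in any step. The sum of the FPKM of a library rises with the share of reads on short genes and was 374509 to 380140 under DMSO and 413739 to 420687 under BRQ.

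FPKM are not counts, so they were tested on a log scale. Because the values of a gene in a library are whole multiples of the worth of a single read, the reads behind them were recovered, up to a common divisor per gene, from the steps between values. Whole reads, within 0.02 to 0.08 reads, were obtained for all 10552 tested genes and all 63312 of their values. On simulated FPKM the recovery gave the true reads for 98.2% of 2273 genes with a mean of at least 50 reads. The recovered depths ranged from 30942871 to 34053453 reads per library, the median tested gene had a mean of 1634 reads, and the lowest had 14. The 10 most abundant genes of a library took 3.45% to 3.71% of its reads. Recovered reads were used for depth, for 95% Wilson intervals of shares of reads, for the comparison of replicates by chi-square and for an alternative test.

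Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(FPKM + 1), two-sided, with no covariates, and called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Fold changes are BRQ against DMSO. The 40 fixed lists cover pathways that a DHODH inhibitor could touch in a breast cancer line and markers of other cell types. Of their entries 1066 were found by symbol, 16 by an older symbol, and 31 were not in the table. Lists with at least 4 tested genes (34) were tested against all other tested genes with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. The table's ontology terms and pathways with 10 to 300 tested genes (2983) were tested in the same way. Members of a list were also counted with p adjusted over the list alone.

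The named genes are Dhodh, Cad and Umps, the 10 genes with the largest rise and the 10 with the largest fall among called genes with separate groups, a mean of at least 5 FPKM in the higher group and a symbol that is not a predicted or clone name, and members of the lists. From a called list come the 3 members with the largest change in its direction and the largest change against it, from an uncalled list the called member with the largest change, and from a list of another cell type the member with the highest mean. Some members of lists were left out for length or are not reported here, and genes outside this rule are marked as such.

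In data simulated from the 6 libraries, limma recovered 76.1% of genes changed 1.2-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold, with 9 false calls among 10352 unchanged genes. Most genes were unchanged there, rises and falls were balanced, and all genes had the same dispersion (0.0015). These rates therefore do not cover data in which most genes change or the median fold change shifts. Camera found 10 of 10 lists changed 1.3-fold, some raised and some lowered, and called 0 of 40 unchanged lists. Genes were drawn independently there, so this result does not cover lists of correlated genes.

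Alternatives fixed beforehand were a pseudocount of 0.1, no filter and a filter at 5 FPKM, rescaling by median ratios or TMM factors, quantile normalization, the replicate number as a block, each library left out in turn and a robust prior. Alternatives added after the data were seen were limma-voom on the recovered reads, the DMSO libraries with BRQ replicate 1 only, and the test without the genes of a hepatocyte list (58 genes) and a macrophage list (62 genes), both written after their transcripts were noticed. Erythroid markers and mitochondrially encoded genes of the fixed lists gave no tested gene.

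Genomic span and transcript GC content came from a reference annotation of another mouse build, GRCm38, matched by symbol or Entrez identifier, and were found for 99.8% and 99.5% of tested genes. Exonic length, on a relative scale, was derived from the steps between the deposited FPKM values and was obtained for 100% of them. No coordinates are given because the builds differ. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.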

Results

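Gene expression was measured by RNA sequencing in 6 libraries of 4T1, a mouse breast cancer cell line, 3 from cells given DMSO, the solvent control, and 3 from cells given BRQ. The series title names an inhibitor of DHODH, the mitochondrial enzyme that oxidises dihydroorotate to orotate in de novo pyrimidine synthesis, and the comparison asks how BRQ altered gene expression in these cells. The labels used here state neither dose nor duration. All 6 sample titles also carry the letters DHO, which the labels do not explain, so whether a further compound was present in both groups is open. The deposited table listed FPKM for 18057 genes, and 876 of them stood at 0 in every library. The reads recovered from these values amounted to 30942871 in DMSO replicate 2, the shallowest library, and 34053453 in BRQ replicate 3, the deepest. Mean depth was 32865402 ± 1665019 reads under DMSO and 33678589 ± 578051 under BRQ (SD, n = 3). Replicates of one group correlated across genes, which are not independent replicates, with Pearson's r of 0.9962 to 0.9974, against 0.933 to 0.939 between libraries of different groups. Every pair of replicates differed by more than the noise of counting reads (chi-square per gene of 4.71 to 5.55), so none was treated as a library deposited again, though repeated preparations from a single culture would differ too.

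BRQ changed the expression of most genes of 4T1 cells. Transcripts of Dhodh and Umps, which act in de novo pyrimidine synthesis, rose 2.19-fold and 2.97-fold. As groups, genes of DNA replication and G1/S, of oxidative phosphorylation and of autophagy and lysosomes were higher under BRQ at camera's preset correlation. So were immediate early genes, p53 target genes and genes of cholesterol synthesis. No list was called with an estimated correlation (lowest adjusted p = 0.135). Genes of G2/M and mitosis, interferon-stimulated genes, targets of TGF-beta and YAP, and histone genes were lower. With an estimated correlation none of these 10 list calls held either way, and the histone call was also lost under 6 alternatives. The estimate exceeded the preset 0.01 for oxidative phosphorylation (0.22), interferon-stimulated genes (0.129), TGF-beta and YAP targets (0.06) and p53 targets (0.0147). It lay below 0.01 for the other called lists, so a larger correlation among members cannot account for their lost calls. Of 10552 genes tested with limma, 8698 (82.4%) passed an adjusted p of 0.05, with 5143 higher and 3555 lower under BRQ, and the 3 BRQ values of 8837 genes (83.7%) did not overlap the 3 DMSO values, against 10% by chance. A change of at least 2-fold was found for 1055 genes, of which 752 were higher and 303 lower. The median absolute log2 fold change was 0.41, with a median SE of 0.053. The median signed log2 fold change over all tested genes was 0.12, and the split between higher and lower genes followed this shift: it was 4250 higher to 4432 lower after quantile normalization. After median-ratio, TMM and quantile scaling, 24 of the 34 tested lists had fewer genes higher and 26 more genes lower in every case. Log2 fold changes of single genes are given on the log2(FPKM + 1) scale, which understates changes of low genes, while n-fold changes of single genes are ratios of mean FPKM. Both include this shift, and medians of gene groups are given relative to it.

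BRQ replicates 2 and 3 stood apart from the other 4 libraries in transcripts of hepatocytes and macrophages. A list of hepatocyte genes took 107.9 ± 3.85 RPM, the recovered reads scaled to library depth, under DMSO (SD, n = 3) and 91.4 (95% Wilson interval 88.2 to 94.7) in BRQ replicate 1. It took 31.5 (29.6 to 33.4) in BRQ replicate 2 and 26.7 (24.99 to 28.5) in BRQ replicate 3. Most of what remained there was Fah, named after its values were seen, which took 31.4 ± 1.15 RPM under DMSO and 20.8, 19.9 and 17.4 in BRQ replicates 1, 2 and 3. Without it the list took 76.5 ± 2.7 RPM under DMSO, 70.6 in BRQ replicate 1, 11.5 in BRQ replicate 2 and 9.22 in BRQ replicate 3. A list of macrophage genes took 80.1 ± 2.995 RPM under DMSO and 129.8 (126 to 134) in BRQ replicate 1, against 308 (302 to 314) in BRQ replicate 2 and 300.1 (294 to 306) in BRQ replicate 3. Without Cd68, its most abundant gene, it took 53.6 ± 2.41 RPM under DMSO and 66.8, 231 and 233 in BRQ replicates 1, 2 and 3. These intervals cover counting error only. With BRQ replicate 1 as the sole BRQ library, assumed to vary like the DMSO libraries, limma called 7725 of 10505 genes, 4562 higher and 3163 lower. Of the 8605 genes called with all 6 libraries and tested here, 7612 were called in the same direction and 1, Lyz2, in the opposite direction. At camera's preset correlation the 10 gene groups called with all 6 libraries were called there too, with adjusted p between 6.6e-05 and 0.0246, while none was called with an estimated correlation over the 6 libraries. The same direction and call were found for each named gene called with all 6 libraries and tested there. The labels name no batch, and no DMSO library shared the levels of BRQ replicates 2 and 3, so these 2 libraries could not be compared with DMSO libraries like them in these transcripts.

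**Figure D1:**
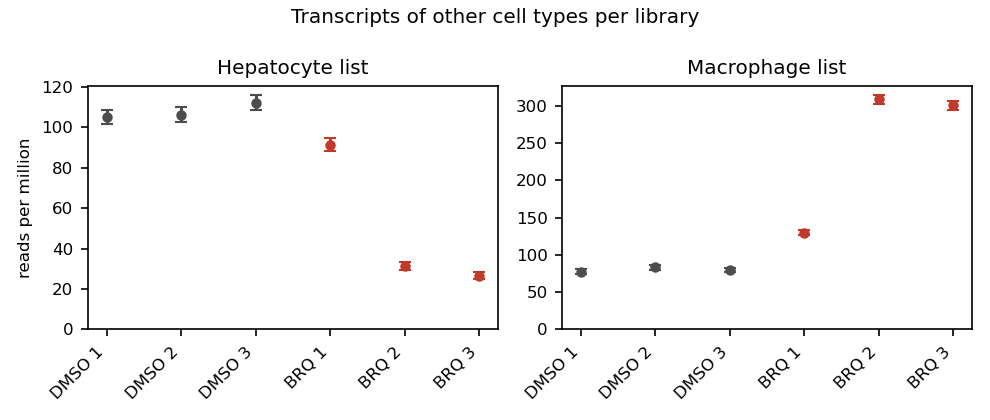
RPM of the hepatocyte list and the macrophage list in each of the 6 libraries, with bars for 95% Wilson intervals, which cover counting error only. BRQ replicate 1 (91.4 hepatocyte and 129.8 macrophage RPM) lay closer to the DMSO libraries than to BRQ replicates 2 and 3.

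In de novo pyrimidine synthesis, the pathway of the enzyme named in the title, Dhodh rose from 10.97 ± 0.473 to 24.1 ± 1.55 FPKM (SD, n = 3; log2 fold change 1.07, SE 0.0542, limma adjusted p = 4.31e-08). Umps, which converts orotate to UMP, rose from 24.1 ± 1.13 to 71.5 ± 1.46 FPKM (log2 fold change 1.53, SE 0.0395, adjusted p = 9.32e-10). Cad, which catalyses the opening steps of the pathway, measured 39.0 ± 0.842 FPKM under DMSO and 38.0 ± 0.818 under BRQ (log2 fold change -0.03, SE 0.0335, adjusted p = 0.359). It was called lower after median-ratio, TMM and quantile scaling (-0.16, -0.16 and -0.23). Of the 14 tested genes of this list, 9 were higher and 4 lower, over all genes and adjusted over the list alone. The list as a whole was not called (median 0.31 above that of all genes, camera adjusted p = 0.361, adjusted p = 0.759 with an estimated correlation). Among 14 genes of pyrimidine salvage and breakdown 8 rose and 3 fell (camera adjusted p = 0.448), and Uck1, which phosphorylates uridine and cytidine, rose from 20.1 ± 1.01 to 51.1 ± 2.62 FPKM. Of 3 nucleoside transporters, too few to test as a list, 2 rose, among them Slc29a1 (20.2 ± 0.891 to 28.8 ± 0.37 FPKM), and 1 fell. Lists that draw on pyrimidine nucleotides or share their precursors were not called. UDP-sugar and hexosamine synthesis had 10 of 16 genes higher and 2 lower (adjusted p = 0.438), and 7 to 8 higher and 5 lower under the 3 other scalings. Phospholipid synthesis through CDP had 8 of 16 higher and 3 lower (0.641), and de novo purine synthesis 5 of 13 higher and 6 lower (0.448), which became 3 and 8 under the 3 other scalings. Their members Pcyt2 (16.4 ± 0.728 to 30.7 ± 0.724 FPKM) and Prps1 (53.7 ± 0.197 to 91.6 ± 1.59 FPKM) rose.

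**Figure D2:**
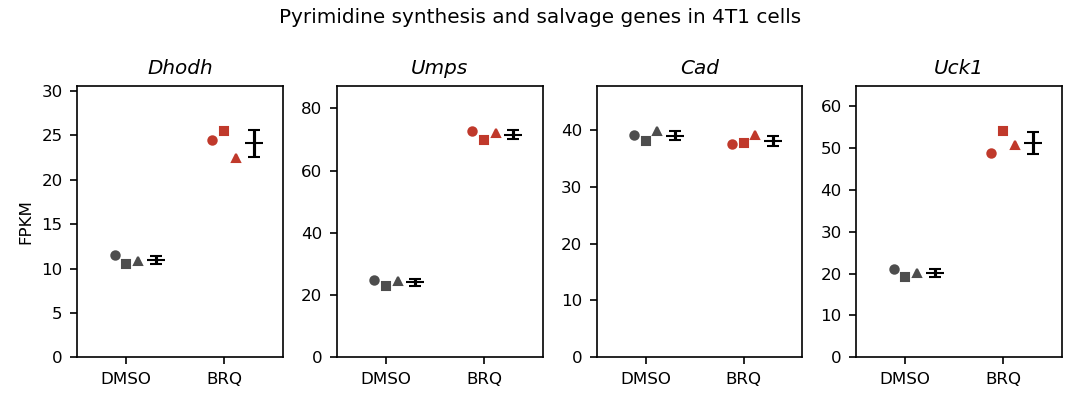
FPKM of Dhodh, Umps, Cad and Uck1 in each DMSO and BRQ library (points, one marker shape per replicate number), with the mean and SD of each group (n = 3). The BRQ means of Dhodh (24.1), Umps (71.5) and Uck1 (51.1) lay above the DMSO means (10.97, 24.1 and 20.1), while Cad measured 39.0 and 38.0, a difference called lower only under the 3 other scalings.

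The 10 genes with the largest rises were led by Fos. This immediate early transcription factor gene went from 1.06 ± 0.307 to 19.3 ± 1.148 FPKM (18.2-fold; log2 fold change 3.31, SE 0.0975, limma adjusted p = 1.66e-09). Hexim1, an inhibitor of the elongation kinase P-TEFb, increased 9.8-fold to 41.8 ± 1.64 FPKM (3.02, SE 0.0505, adjusted p = 1.28e-10). Btg2, an antiproliferative p53 target, reached 16.0 ± 0.255 FPKM from 1.1 ± 0.109, and Ccne1, which encodes cyclin E1, reached 53.3 ± 0.195 from 8.59 ± 0.411. The stress transcription factor Atf3 rose 6.52-fold to 91.1 ± 1.79 FPKM, and the triglyceride synthesis gene Dgat2 rose 11.2-fold to 22.5 ± 1.42. Arl4d (log2 fold change 2.77), Csf2, which encodes the cytokine GM-CSF (2.41), and Adamts4 (2.36) rose as well. Tnf, a cytokine that macrophages also make, completed the set: it measured 1.43 ± 0.453 FPKM under DMSO, 6.54 in BRQ replicate 1, 17.0 in BRQ replicate 2 and 16.1 in BRQ replicate 3. Its log2 fold change was 2.46 (SE 0.288, adjusted p = 2.02e-05), and 1.65 (SE 0.198, adjusted p = 0.00018, range over all alternatives 1e-07 to 0.00286) with BRQ replicate 1 as the sole BRQ library.

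The 10 largest falls were led by Mipol1 (10.5 ± 1.522 to 0.913 ± 0.525 FPKM; log2 fold change -2.62, SE 0.177, limma adjusted p = 3.24e-07) and the linker histone gene H1f2 (10.2 ± 1.15 to 0.908 ± 0.339 FPKM). Eif4a2, a helicase of translation initiation, was 5.28-fold lower (77.7 ± 1.36 to 14.7 ± 0.439 FPKM; -2.32, SE 0.0351, adjusted p = 1.28e-10). Tia1, an RNA-binding protein of stress granules, was 5.91-fold lower (15.8 ± 0.834 to 2.67 ± 0.0932 FPKM). Ogt, which transfers N-acetylglucosamine from UDP-GlcNAc to proteins, was 4.27-fold lower (43.9 ± 1.2 to 10.3 ± 0.515 FPKM). Ankrd1, a YAP target, dropped from 145 ± 3.24 to 38.7 ± 1.32 FPKM. The remaining genes were Sbf2 (log2 fold change -2.39), Lipg (-2.29), Cpne1 (-2.28) and Hmgxb4 (-2.04).

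**Figure D3:**
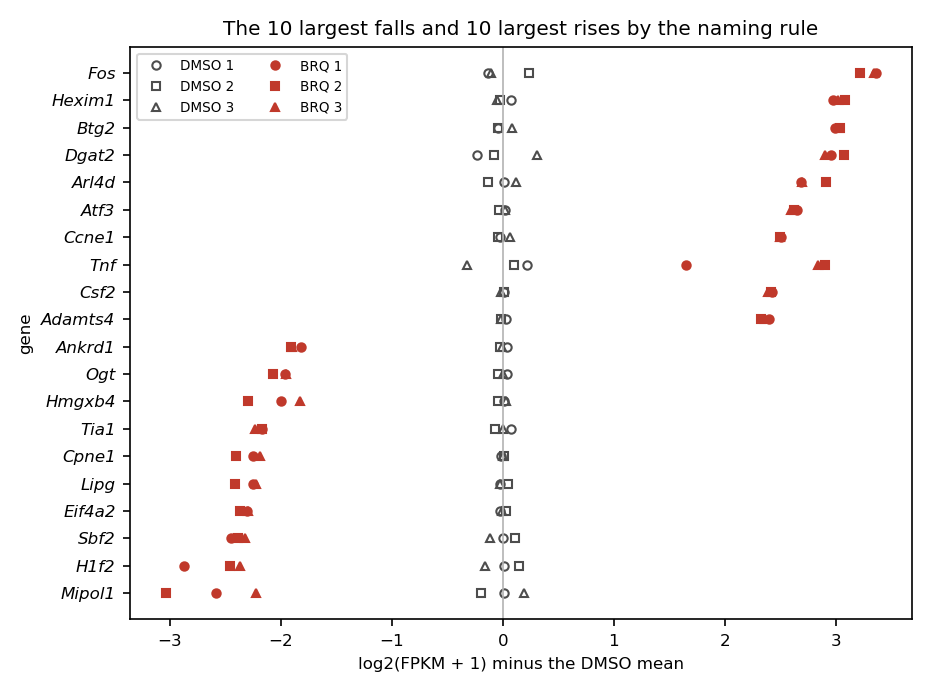
The 10 largest rises and 10 largest falls, drawn per library as log2(FPKM + 1) minus the DMSO mean. Genes were chosen among those with all BRQ points on one side of all DMSO points, so this separation is not a result. They ran from Fos (mean log2 fold change 3.31) to Mipol1 (-2.62), and BRQ replicate 1 lay below the other BRQ libraries for Tnf.

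Genes of the cell cycle moved in opposite directions. Of 48 genes of DNA replication and G1/S, 41 rose and 4 fell, the same counts adjusted over the list alone (37 and 6 to 8 under the 3 other scalings), and the list median lay 0.54 above that of all genes (camera adjusted p = 5.01e-05, adjusted p = 0.135 with an estimated correlation). Beside Ccne1, the flap endonuclease gene Fen1 rose from 27.3 ± 1.58 to 107 ± 0.804 FPKM. E2f8, a repressor of E2F targets, fell from 28.0 ± 0.101 to 17.4 ± 0.556. Of 40 genes of G2/M and mitosis, 26 fell and 8 rose, over all genes and adjusted over the list alone, and 30 to 31 fell and 5 to 6 rose under the 3 other scalings (median -0.33 relative to all genes, camera adjusted p = 0.00172, adjusted p = 0.135 with an estimated correlation). Top2a, which encodes topoisomerase II alpha, fell 2.47-fold from 227 ± 3.62 to 91.6 ± 2.16 FPKM. The cytokinesis genes Anln and Ect2 fell from 125 ± 1.6 to 51.5 ± 1.77 and from 66.6 ± 1.2 to 34.7 ± 1.01 FPKM. Pttg1, which encodes securin, rose against the list (36.2 ± 1.07 to 74.7 ± 2.09 FPKM). Of 45 genes of the histone list in the table only 5 reached the level for testing. All 5 fell, also adjusted over the list alone, with a median of -1.04 relative to all genes (camera adjusted p = 0.0306, adjusted p = 0.273 with an estimated correlation). This call was lost without DMSO replicate 3 (adjusted p = 0.054), without BRQ replicate 3 (0.0606), under limma-voom (0.0545) and under the 3 other scalings (0.0677 to 0.0857), with a range over all alternatives of 0.0115 to 0.0857. Not relative to all genes, the list's median log2 fold change was -0.93 and ranged from -1.69 under limma-voom to -0.11 without a filter. One of the 5, H1f0, named after its values were seen, encodes a linker histone that is also made outside S phase. Whether poly(A) or total RNA was sequenced is not given, so how fully histone transcripts were captured is unknown. H2bc4 (5.46 ± 0.893 to 1.82 ± 0.888 FPKM) and H4c12 (1.85 ± 0.324 to 0.525 ± 0.391 FPKM), like H1f2, belong to families of near-identical copies, and their values are uncertain because reads may be shared among these. The checkpoint list was not called, with 15 of 34 genes higher and 13 lower (adjusted p = 0.893), nor were MYC targets, with 12 of 37 higher and 21 lower (adjusted p = 0.167). Rad51ap1, a recombination factor, rose from 12.5 ± 0.674 to 27.8 ± 0.51 FPKM, and the MYC target Pcna, which encodes the sliding clamp of DNA polymerases, rose from 157 ± 1.82 to 387 ± 2.4.

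Targets of p53 and immediate early genes rose. Of 35 p53 targets 25 rose and 2 fell, over all genes and adjusted over the list alone (21 and 4 to 6 under the 3 other scalings), with a median 0.26 above that of all genes (camera adjusted p = 0.012, adjusted p = 0.27 with an estimated correlation). They included Btg2, the cyclin-dependent kinase inhibitor gene Cdkn1a (11.5 ± 0.554 to 47.7 ± 3.34 FPKM; log2 fold change 1.96, SE 0.055, limma adjusted p = 1.25e-09) and the kinase gene Plk3 (22.3 ± 0.183 to 59.0 ± 3.64 FPKM). Polk, a translesion polymerase gene, fell from 10.1 ± 0.659 to 6.92 ± 0.311. Btg2 also belongs to the immediate early list. Activity of p53 was not measured, so whether the rises of its targets came through p53 was not tested. Of 20 immediate early genes 17 rose and 2 fell, again the same adjusted over the list alone, with a median 0.94 above that of all genes (camera adjusted p = 0.00477, adjusted p = 0.177 with an estimated correlation). Fos, Btg2 and Atf3 led this list, and Klf6 fell from 67.4 ± 0.409 to 29.98 ± 0.871 FPKM. ATF4 targets of the integrated stress response divided into 14 higher and 21 lower of 38 (adjusted p = 0.167), with a median of -0.19 before the shift is taken off but a mean of 0.006. The unfolded protein response (16 of 24 higher, 5 lower, adjusted p = 0.159), NRF2 targets (13 of 20 higher, 3 lower, 0.174, and 9 to 11 higher and 6 to 8 lower under the 3 other scalings) and senescence-associated genes (12 of 15 higher, 3 lower, 0.174) were not called, though the unfolded protein response was without a filter (0.0372, range over all alternatives 0.0372 to 0.233). Nor were apoptosis regulators (17 of 26 higher, 6 lower, adjusted p = 0.239) and heat shock genes (7 of 14 higher, 5 lower, 0.893). In these lists the chaperone gene Dnajb9 rose from 10.7 ± 0.779 to 41.0 ± 1.23 FPKM, Osgin1 from 14.4 ± 0.791 to 48.8 ± 1.45 and the BH3-only gene Bad from 15.4 ± 0.727 to 39.9 ± 2.46. The constitutive chaperone gene Hspa8 fell from 729 ± 33.6 to 220.1 ± 9.22.

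Mitochondrial, lysosomal and sterol genes were higher. Of 58 nuclear genes of oxidative phosphorylation 51 rose and 7 fell, over all genes and adjusted over the list alone, with a median 0.39 above that of all genes (camera adjusted p = 0.000135, adjusted p = 0.437 with an estimated correlation). Its largest rises were those of complex I subunits, which pass electrons from NADH into the respiratory chain: Ndufb10 went from 59.2 ± 3.11 to 136 ± 8.59 FPKM, Ndufa1 from 40.8 ± 2.94 to 88.2 ± 11.2 and Ndufs3 from 52.7 ± 3.2 to 99.9 ± 4.26. Atp5g2, a subunit of ATP synthase, fell from 160.3 ± 3.91 to 117 ± 6.31. These genes are short (median genomic span 7.32 kb, against 22.6 kb for all genes), and fold changes fell with span across genes, which are not independent replicates (Spearman's rho -0.495). Adjusted for span, exonic length and GC content, the list's relative median was 0.14 (adjusted p = 0.0436), and those of immediate early genes and p53 targets were 0.57 (6.26e-05) and 0.16 (0.0335). The autophagy and lysosome list had 29 of 34 genes higher and 3 lower, the same adjusted over the list alone (median 0.36 above that of all genes, camera adjusted p = 0.000906, adjusted p = 0.135 with an estimated correlation). The sialidase gene Neu1 rose from 7.41 ± 0.355 to 25.6 ± 1.47 FPKM and the autophagosome gene Map1lc3b from 52.4 ± 0.846 to 149 ± 6.43. The lysosomal channel gene Mcoln1 rose from 23.7 ± 0.95 to 56.8 ± 0.16 FPKM, and Sqstm1, an autophagy receptor gene, fell from 164 ± 2.45 to 107 ± 4.93. With BRQ replicate 1, which lacked most of the macrophage transcripts of the other BRQ libraries, as the sole BRQ library, 27 of the 34 were higher and 2 lower (adjusted p = 0.00118, range over all alternatives 1.98e-05 to 0.0016). Cholesterol synthesis had 18 of 24 genes higher and 3 lower, the same adjusted over the list alone (median 0.34 above that of all genes, camera adjusted p = 0.0263, adjusted p = 0.27 with an estimated correlation). Acat2 rose from 17.4 ± 1.41 to 57.1 ± 0.527 FPKM and Insig1 from 9.61 ± 0.547 to 31.9 ± 1.55. This list was no longer called after the same adjustment (relative median 0.29, adjusted p = 0.058). Glycolysis (6 of 18 higher, 6 lower, adjusted p = 0.798, and 4 to 6 higher and 10 to 11 lower under the 3 other scalings), the hypoxia response (11 of 20 higher, 7 lower, 0.893) and ferroptosis defence (14 of 25 higher, 8 lower, 0.874) were not called. Slc7a11, the cystine transporter gene of the ferroptosis list, fell from 1.82 ± 0.117 to 0.26 ± 0.0487 FPKM. Cytosolic ribosomal proteins had 19 of 77 genes higher and 34 lower (18 and 34 adjusted over the list alone, 13 to 21 and 44 to 57 under the 3 other scalings) and were not called (camera adjusted p = 0.0931, adjusted p = 0.84 with an estimated correlation, which was 0.57). At the preset correlation they were called lower after median-ratio (0.00378) and TMM scaling (0.00341), without DMSO replicate 1 (0.0341) and without BRQ replicate 2 (0.0485), with a range over all alternatives of 0.00341 to 0.206. Ribosome biogenesis had 31 of 59 higher and 20 lower (adjusted p = 0.893, and 22 to 26 higher and 25 lower under the 3 other scalings), and its member Npm1, which encodes nucleophosmin, fell from 654 ± 18.2 to 294 ± 5.9 FPKM.

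Interferon-stimulated genes were lower: 25 of 44 fell and 11 rose, over all genes and adjusted over the list alone (median -0.41 relative to all genes, camera adjusted p = 0.00696, adjusted p = 0.437 with an estimated correlation). Oas2, a sensor of double-stranded RNA, fell from 49.1 ± 3.49 to 15.5 ± 0.516 FPKM. Samd9l fell from 30.5 ± 0.75 to 12.6 ± 0.956 and the antiviral gene Rsad2 from 36.7 ± 1.53 to 17.8 ± 4.22. Irf7, a transcription factor of the interferon response, rose from 288 ± 0.634 to 629.7 ± 5.33. MHC class I antigen presentation had 15 of 23 genes higher and 2 lower (12 to 13 and 6 to 8 under the 3 other scalings). It was not called (camera adjusted p = 0.0931, adjusted p = 0.437 with an estimated correlation). At the preset correlation it was called higher without a filter (0.0142) and under limma-voom (0.0193, range over all alternatives 0.0142 to 0.251). Its member Calr, which encodes calreticulin, rose from 463 ± 12.9 to 956 ± 7.78 FPKM. Immune ligands and checkpoints had 5 of 10 higher and 5 lower (0.537), with Tnfsf9, the 4-1BB ligand gene, up from 7.01 ± 0.639 to 22.6 ± 0.876 FPKM. NF-kB targets, cytokines and chemokines had 20 of 32 genes higher and 7 lower (adjusted p = 0.174, 0.23 with BRQ replicate 1 as the sole BRQ library, and 0.0721 to 0.358 over all alternatives). All 4 tested leukocyte markers rose with all 6 libraries (camera adjusted p = 0.239 as a list, adjusted p = 0.677 with an estimated correlation, which was 0.74). At the preset correlation the list was called without BRQ replicate 1 (0.0482, range over all alternatives 0.0482 to 0.488). Cd68 went from 21.1 ± 2.36 FPKM under DMSO to 50.2, 61.2 and 53.3 in BRQ replicates 1, 2 and 3. With BRQ replicate 1 as the sole BRQ library, 2 of the 3 then tested rose and Lyz2 fell. This lysozyme gene, abundant in macrophages and named after its values were seen, was at 4.89 ± 0.471 FPKM under DMSO, 3.56 in BRQ replicate 1, 35.4 in BRQ replicate 2 and 36.4 in BRQ replicate 3.

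Targets of TGF-beta and YAP fell in 13 of 19 cases and rose in 3, over all genes and adjusted over the list alone (median -0.46 relative to all genes, camera adjusted p = 0.012, adjusted p = 0.334 with an estimated correlation). Beside Ankrd1, the tissue factor gene F3 fell from 24.5 ± 1.28 to 12.8 ± 1.37 FPKM and the matricellular gene Ccn1 from 397 ± 9.23 to 227 ± 3.41, and Id2 rose from 24.0 ± 1.07 to 53.9 ± 0.404. Epithelial and keratin genes (7 of 20 higher, 12 lower, adjusted p = 0.104) and mesenchymal genes (9 of 20 higher, 10 lower, 0.283, and 5 to 6 higher and 10 to 11 lower under the 3 other scalings) were not called, except that the epithelial list was called lower with the filter at 5 FPKM (0.0351, range over all alternatives 0.0351 to 0.147). Vim, which encodes the mesenchymal filament protein vimentin, fell from 1238 ± 34.8 to 459.7 ± 6.3 FPKM, and Elf3, an epithelial transcription factor gene, rose from 19.6 ± 1.42 to 75.3 ± 2.04. Of the neural crest list 1 of 3 tested genes rose and 2 fell, among them Map2 (4.76 ± 0.292 to 1.48 ± 0.0941 FPKM). Single markers were tested for fibroblasts, Pdgfra (4.39 ± 0.0935 to 7.77 ± 0.446 FPKM, adjusted p = 1.27e-06), and endothelium, Flt1 (3.52 ± 0.156 under DMSO and 3.08 ± 0.227 under BRQ, adjusted p = 0.0619). Each list had 10 markers in the table and only 1 tested, so neither gene speaks for its cell type. Among untested fibroblast markers, named after their values were seen, Fap rose (0.538 ± 0.0707 to 0.754 ± 0.144 FPKM) and Col6a3 fell (1.41 ± 0.142 to 0.227 ± 0.0541). The untested endothelial marker Tie1, named in the same way, rose (0.122 ± 0.0208 to 0.766 ± 0.128 FPKM). Flt1 was called lower without BRQ replicate 3 (log2 fold change -0.20, adjusted p = 0.0312, range over all alternatives 0.00509 to 0.174), under limma-voom (-0.19) and under the 3 other scalings (-0.25, -0.25 and -0.19).

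**Figure D4:**
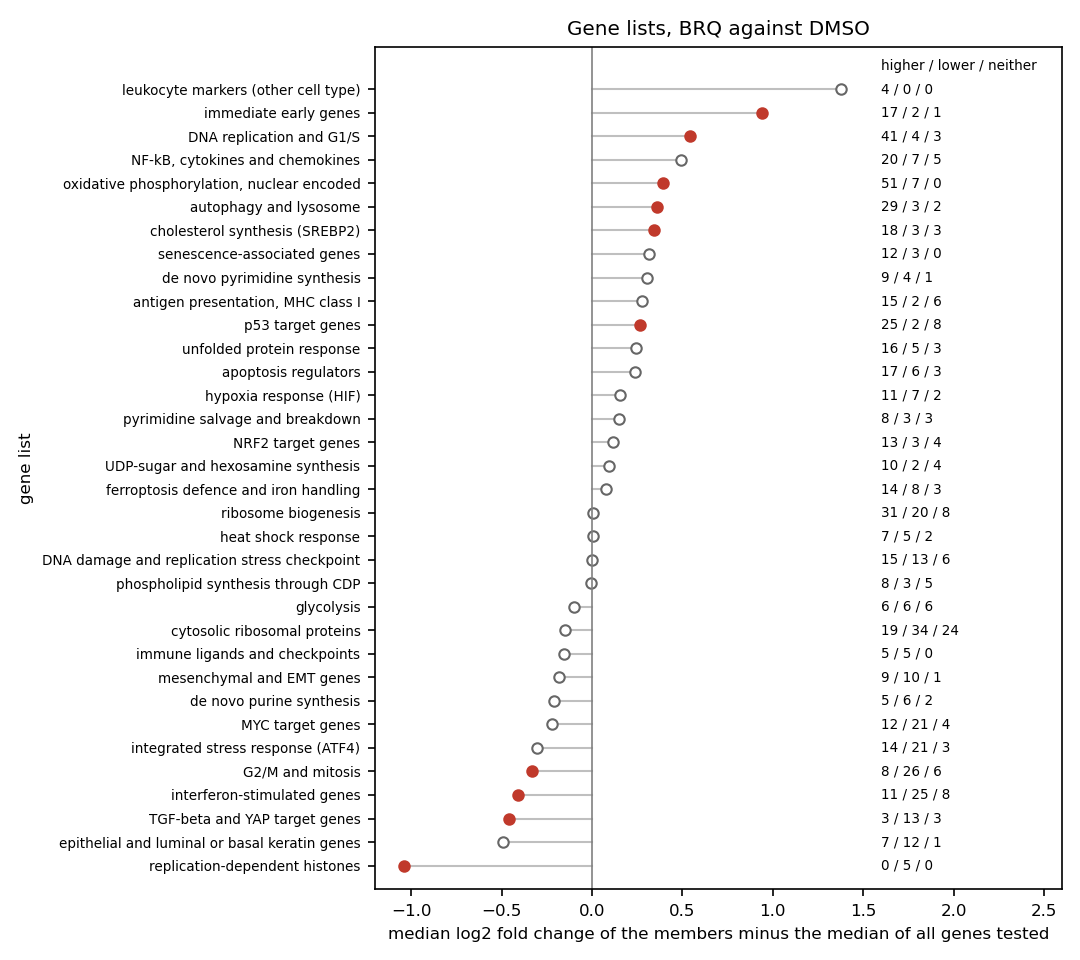
Median log2 fold change of each of the 34 tested gene lists relative to the median of all genes, with filled points for the 10 lists called by camera with its preset correlation and the numbers of members higher, lower and neither at the right. The 6 lists called higher lay between 0.26 and 0.94, and the 4 called lower between -1.04 and -0.33, while at the same correlation the cytosolic ribosomal proteins were called lower under median-ratio and TMM scaling and without DMSO replicate 1 or BRQ replicate 2.

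With an estimated correlation camera called 0 of 34 lists at an adjusted p of 0.05 and 6 at an unadjusted p of 0.05, fry called 27 lists, and other splits of the 6 libraries into 3 and 3 called up to 11 lists. Nothing in the labels says that the libraries came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.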

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

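The tests with limma-voom, with BRQ replicate 1 as the sole BRQ library and without the hepatocyte and macrophage lists were chosen after the data were seen. Over 17 alternatives the genes changed numbered 6984 to 9534, those higher 4235 to 5697 and those lower 2749 to 4432, all within 1.5 times the reported counts, and the log2 fold change of Dhodh ranged from 0.93 to 1.13 and kept its call. Leaving out each library in turn gave 8385 to 8487 genes changed, 4969 to 5065 higher, 3405 to 3439 lower, 1024 to 1083 changed at least 2-fold, 9 to 11 lists, 180 to 198 terms and 1.03 to 1.12 for Dhodh. Genes changed at least 2-fold numbered 824 to 1500 under 16 of the 17 alternatives and 1584 under limma-voom, which adds no pseudocount of 1 FPKM. Terms numbered 176 to 233 under 16 alternatives and 302 under limma-voom, where the cause was not tested. Lists called numbered 9 to 12 under 17 of 19 alternatives, 0 with an estimated correlation (6 at an unadjusted p of 0.05) and 27 with fry, which does not compare a list with other genes. Median-ratio, TMM and quantile scaling reversed 2, 4 and 74 of the 8698 gene calls. Among named genes no call was lost or reversed, and Cad and Flt1 gained one in 8 cases. Among lists, 6 calls were lost, all of histones, and 9 gained under the 17 alternatives that keep camera's preset correlation. Replicate numbers did not pair the libraries: deviations from the group means of libraries with the same number correlated at 0.004, -0.032 and -0.034, and those with other numbers at -0.0035 to 0.037. With the replicate number as a block, 8619 genes changed (5112 higher, 3507 lower), 1056 of them at least 2-fold, with 10 lists and 176 terms. The tests of edgeR and DESeq2 on recovered reads were not run, since the deposited unit is FPKM. Depth limits only low genes, since the lowest tested gene had a mean of 14 reads.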

Other observations

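Of the tests in this part, those on hepatocyte and macrophage transcripts were chosen after the result was seen. The tests on genomic span, on the fixed lists and on other splits of the libraries were chosen before.

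Among 2983 annotated terms, camera called 16 higher and 179 lower at its preset correlation, while the lowest adjusted p was 0.571 with an estimated correlation. No term was adjusted for genomic span, with which fold changes fell across genes (Spearman's rho -0.495). Gene length may therefore carry part of these calls. Terms of gene expression machinery went both ways, and the genes named from terms were chosen after their values were seen. Of 13 genes of the RNA polymerase II core complex 12 rose and 1 fell (adjusted p = 0.0268): Polr2a, its catalytic subunit, went from 36.8 ± 0.575 to 128.8 ± 2.74 FPKM (SD, n = 3). Polr2l rose from 17.2 ± 0.173 to 54.0 ± 3.01 FPKM, against a small fall of Polr2m (log2 fold change -0.13). Both subunits of the mitochondrial ribosome were higher, with 47 of 59 genes up and 4 down in the large subunit (adjusted p = 0.00287) and 23 of 29 up and 2 down in the small (0.0342). Single-stranded DNA helicases rose in 14 of 15 cases, none falling, and all 12 genes of lysosomal lumen acidification rose (0.0433). The term for regulation of mRNA splicing via the spliceosome had 13 of 14 genes lower and 1 higher (adjusted p = 0.00289). Larger splicing terms were more mixed, with 28 of 39 genes lower and 9 higher for regulation of alternative mRNA splicing (0.0167) and 25 of 38 lower and 10 higher for regulation of RNA splicing (0.0483). Stress granule genes fell in 39 of 59 and rose in 14 (0.00551). In the RISC complex 9 of 13 genes fell and none of the others was called by limma (adjusted p = 0.0117). Ago2, the slicing argonaute, fell from 40.3 ± 0.917 to 20.2 ± 1.94 FPKM, Tnrc6a from 11.5 ± 0.723 to 5.16 ± 0.253 and Dicer1 from 11.9 ± 0.525 to 6.67 ± 0.417.

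Genes of the contractile and adhesive machinery were lower, again without adjustment for genomic span. Focal adhesion had 79 of 126 genes lower and 27 higher (camera adjusted p = 0.000294, adjusted p = 0.571 with an estimated correlation). Actomyosin structure organization had 19 of 24 lower and 3 higher (0.00157), and the apical junction complex 19 of 23 lower and 2 higher (0.00215). The TGF-beta pathway had 38 of 59 lower and 14 higher (adjusted p = 0.00755) and ECM-receptor interaction 25 of 38 lower and 9 higher (0.00755). Myh9, a heavy chain of non-muscle myosin, fell from 203 ± 5.77 to 94.2 ± 2.19 FPKM (log2 fold change -1.10, SE 0.0302, limma adjusted p = 1.09e-09). Zyx, a focal adhesion gene, fell from 47.0 ± 1.12 to 25.7 ± 0.506, and Tjp1, a tight junction gene, from 34.5 ± 0.33 to 20.2 ± 0.901.

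Hepatocyte and macrophage transcripts parted BRQ replicates 2 and 3 from the other 4 libraries: recovered reads of Alb were 465, 552 and 716 under DMSO, 510 in BRQ replicate 1, 6 in BRQ replicate 2 and 0 in BRQ replicate 3, and Lyz2 went the other way. An effect of BRQ on them in the cells stays open, since only BRQ replicate 1 could argue against it: its hepatocyte reads lay 1.65 (log2) above the mean of the other BRQ libraries and -0.24 from DMSO (2.77 and -0.12 without Fah), its macrophage reads -1.23 and 0.70 (-1.80 and 0.32 without Cd68), and the median macrophage gene was 1.70 (log2) higher in the other BRQ libraries and -0.02 from DMSO in BRQ replicate 1. RNA or reads from liver in 4 libraries and from macrophages in the other 2 stay open too: 94% of 50 hepatocyte genes were higher and 82.5% of 57 macrophage genes lower in BRQ replicate 1 than in both other BRQ libraries, but as both lists were written after the transcripts were noticed, all these values restate the pattern. Of the hepatocyte list 13 genes reached the level for testing in 4T1 cells and of the macrophage list 16, including all 4 tested leukocyte markers, and Cd14 and Cd68 were higher in BRQ replicate 1 too (12.4 against 6.35 ± 0.262 and 50.2 against 21.1 ± 2.36 FPKM under DMSO). Whether such reads entered with the cells, at library preparation or at sequencing was not tested, and the labels name no batch.

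Fold changes fell with the genomic span of the gene (Spearman's rho -0.495 across genes, which are not independent replicates): 73.3% of 1216 genes under 5 kb were higher and 12.6% lower, against 9.89% higher and 75.4% lower of 1122 genes over 100 kb. A bias with exonic length or with GC content is argued against as the whole cause, as the relation remained given exonic length (partial rho -0.322) and given GC content (-0.458). Since rho was nearer to 0 given exonic length, a part carried by such a bias stays open. Slower transcription through long genes under BRQ may contribute, as the relation also remained given exonic length, GC content and mean level together (-0.295). Pairs of libraries within a group had rho of -0.137 to 0.228, so span also tracks some variation between replicates, while each BRQ library against the DMSO mean gave -0.503 to -0.479. Neither nascent RNA nor elongation was measured, so changes in the stability of transcripts stay open.

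The fixed lists differ in gene length and composition, and span, exonic length and GC content together accounted for 27.4% of the variance of fold changes. Of the 10 called lists, 9 were called in the same direction on residual gene statistics. On unadjusted statistics tested in the same form 9 were called, 8 of them on both. This speaks against these properties as the whole cause for those 8 lists other than oxidative phosphorylation and p53 targets. Their residual calls lay near the threshold (adjusted p = 0.0436 and 0.0335) at the preset correlation, while that of oxidative phosphorylation was estimated at 0.22. Histones were called on the residuals alone, and cholesterol synthesis lost its call (adjusted p = 0.058) although its median relative to all genes went only from 0.34 (interquartile range 0.753) to 0.29 (0.607), a small loss that took an adjusted p near the threshold past it. For oxidative phosphorylation the relative median went from 0.39 (0.342) to 0.14 (0.29) and for immediate early genes from 0.94 (1.01) to 0.57 (1.09). For p53 targets it went from 0.26 (0.556) to 0.16 (0.569). All of these kept the call, and there these properties may carry at least part of the rise. Of the other lists, cytosolic ribosomal proteins (adjusted p = 1.4e-11, at a preset correlation of 0.01 although theirs was estimated at 0.57), MYC targets (0.00256) and epithelial and keratin genes (0.00362) were called lower on the residuals alone, mesenchymal genes lower on both statistics (0.0374 unadjusted, 0.0344 on residuals), and MHC class I (0.00943), the unfolded protein response (0.0346), NRF2 targets (0.0346) and NF-kB targets (0.0385) higher on the unadjusted statistics alone.

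The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The split into DMSO and BRQ gave 8698 genes changed, 1055 of them at least 2-fold, and 195 terms, against 0, 0 and 68 in the highest other split, so 1 split was as large in each case. For lists it gave 10 against 11 in the highest other split, and 3 splits were as large. Every other split sets 2 libraries of a group and 1 of the other against the rest and so carries part of the difference between groups.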
